A study of Homo sapiens with 176 samples.

How the data were processed

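Sperm was isolated from frozen and thawed semen, RNA was extracted with Trizol, and small RNA libraries were prepared with the TruSeq small RNA kit and sequenced from a single end. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned with Bowtie 1.0.0 and handled with SAMtools 1.17, and counts were normalised in R 4.2.0 with limma and edgeR 3.40.0. The genome build and the reference sets of miRNA, piRNA and tRNA sequences are not given in the sources used here. The deposited tables, 1 for each class, hold log2 CPM values (reads scaled to library size) that the authors filtered and normalised. For each library the values were checked to follow log2 of a step times a whole number plus a constant, which was the same in all libraries of a class (0.269 CPM for miRNAs, 0.259 for piRNAs and 0.284 for tRNAs). The whole number was taken as the reads of a feature, and 100% of values lay within 0.02 of a whole read. The step gives the effective library size in units of 1e6 reads, which ranged from 0.347 to 29.276 in the miRNA table, from 0.321 to 36.121 in the piRNA table and from 0.256 to 32.59 in the tRNA table. Reads of the listed miRNAs made up a mean of 0.921% of it, those of piRNAs 12.106% and those of tRNAs 1.351%. Features with identical values were each counted in these sums. Among tRNAs 10 rows were identical to an earlier row, some of them of the most abundant genes. The reads and share of tRNAs may thus count the same reads more than once. Reads without molecular identifiers are not independent molecules, so counting error is only part of the error, and errors given here are spreads between libraries or participants. The library with the most features at 0 reads had 81 miRNAs, 368 piRNAs or 18 tRNAs without a read.

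Month, participant and batch were taken from the labels of the libraries. There were 6 columns in each table that matched no sample of the series, and these were left out of every step. Whether the libraries of a participant belong together was checked on the values after the mean of each month in each batch was removed. The median r of pairs of libraries of 1 participant was 0.396 for miRNAs, 0.37 for piRNAs and 0.465 for tRNAs, against -0.121, -0.114 and -0.128 for pairs of different participants of 1 batch, and r exceeded 0.1 in 87.2%, 80% and 82.8% of the pairs of 1 participant. None of the 431 pairs of libraries of 1 participant was a repeat of the same library by reads, with a smallest chi-square per degree of freedom of 3.70 and a median of 34.4. Scores of adverse childhood experiences or stress were not used here.

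The comparisons, tests, lists and named features, with their alternatives, were fixed before the data were examined, except where a setting is said to have been chosen after the data were seen. All tests used the deposited log2 values with limma 3.58.1 in R 4.3.3, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Each class was tested on its own, with Benjamini-Hochberg adjustment within the class at 0.05. Months were compared with limma's moderated F-test and its contrast of month 9 against month 4, and as a slope per month, with participant as a fixed term that also absorbs batch. Refitting with batch in place of participant, or with participant as a random effect, called 0 features between months in each class. Participants were compared within batches with a moderated F-test, with month in the model, and the intraclass correlation was estimated by moments from the nested analysis of variance. Batches were compared over the means of the 30 participants after month means were removed, 5 to a batch. The interaction of batch and month had 25 terms. Two-sided tests were used unless stated otherwise.

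Shared variation was measured on the residuals after participant and month means were removed and each feature was scaled. The share of variance on the first principal component, called the axis, was compared with 1000 shuffles of each feature within participants. The sign of an axis was set so that its mean loading was positive. Axes of different classes were compared with Pearson's r and Spearman's rho and 100000 permutations of libraries within participants.

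Lists held the let-7, miR-34 and miR-449, miR-30 and miR-29 families, the group of miR-10, miR-99, miR-100 and miR-125, the miR-17-92 clusters with their paralogs and the miR-888 cluster. Others held markers of epithelium, leukocytes and erythrocytes, miRNAs named in the literature on paternal stress, and the tRNA isotypes Gly, Glu, Val, Lys, Leu and Ala. All lists were drawn up from general knowledge without a database, and some miRNAs stand in more than 1 list, such as miR-375 and miR-363. Of the testis-enriched X-linked cluster around miR-506, muscle and stromal markers, tRNA-His and mitochondrial tRNAs, 0 members were measured, and of tRNA-Asp 1, so these were not analysed here. Trends of lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Their intraclass correlation, mean pairwise correlation and position on the axis were compared with 10000 random lists matched on size and mean level. Adjustment was over 11 miRNA lists and 6 tRNA lists.

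The features named in the text follow a rule fixed beforehand. For months it took the 3 of each class with the smallest p when none passed. For participants it took the 8 miRNAs, 3 piRNAs and 3 tRNAs with the highest and the 4, 2 and 2 with the lowest intraclass correlation. For batches it took the 6, 3 and 3 with the smallest p, for abundance the 8, 4 and 4 with the highest mean, and for the axis the 5 highest and 5 lowest of each class. Of each list 2 to 4 members were named, and other names were chosen after their values were seen, such as those that passed under an alternative only. Positions of miRNA hairpins come from GENCODE version 29 on GRCh38 by exact name, since the tables hold no coordinates, and 324 of the 338 miRNAs had a hairpin there (95.9%).

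The fits were tested on simulated data with the same design and spread. A difference between months of 1 log2 was called for 96.4% of changed miRNAs, 97% of piRNAs and 100% of tRNAs, and a difference of 0.5 log2 for 53.6%, 64.2% and 66.7%. Intraclass correlations of 0.2, 0.5 and 0.8 were estimated at 0.217, 0.488 and 0.785 for miRNAs, and the simulated axis was recovered with r of 0.995, 0.999 and 0.986 in the 3 classes.

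The alternatives were a fit with batch in place of participant or with participant as a random effect, features with a mean at or above the class median, median centring, quantile normalization, a pseudocount of 1, participants with all 6 months, array weights, robust empirical Bayes with a trend, each batch left out, each participant left out of the batch comparison, ranks, and batch left in the intraclass correlation. For lists they were the estimated correlation, median centring and removal of the axis. Chosen after the data were seen were depth as a covariate (the log2 effective library size of the class), removal of the 18 libraries with under 20000 miRNA reads, identical features counted once, limma with voom weights on the recovered reads, and reads thinned to 20000 miRNA, 200000 piRNA and 20000 tRNA reads in the 158, 159 and 161 libraries that had as many.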

Results

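Small non-coding RNA was sequenced from the sperm of 30 participants who each gave 1 semen sample a month over study months 4 to 9. The deposited tables held libraries from all participants, with 30 each in months 4, 5 and 8, 29 each in months 6 and 7, and 28 in month 9. Of the participants, 27 had all 6 months and 3 had fewer, with 4 months as the fewest. The libraries were made in 6 batches of 5 participants, 28 to 30 libraries a batch, so that each participant belonged to 1 batch and each batch held every month. The title of the series speaks of adverse childhood experiences and current stress, but scores of either were not used here, and no group of participants was formed from the data. The tables held 338 miRNAs, the short regulatory RNAs that guide Argonaute proteins to messenger RNA. They held 1863 piRNAs, the germline RNAs that bind PIWI proteins and silence transposons, and 107 tRNA genes, to which reads of tRNA and its fragments map. Reads recovered from the deposited values ranged from 2319 to 281504 per library for miRNAs (median 90168), from 32249 to 4225445 for piRNAs (median 1205912) and from 4033 to 1031735 for tRNAs (median 109824). Features with identical values were each counted, so the tRNA reads may be too high. In 18 libraries, 2 to 5 in each batch, fewer than 20000 miRNA reads were recovered. Batches 2 and 4 were shallower, with medians of 65238 and 66580 miRNA reads against 102420 to 130498 in the others.

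The most abundant miRNA was miR-10b-5p, transcribed from the HOXD cluster (chromosome 2, 176150303 to 176150412, GRCh38, GENCODE version 29). Its mean was 9.25 ± 0.61 log2 CPM (reads scaled to library size, mean ± SD over all libraries). Next came miR-22-3p with a mean of 9.02 ± 0.56 and miR-12136 with 8.92 ± 1.05. The HOXB miRNA miR-10a-5p averaged 8.63 ± 0.60. Further down stood miR-3960 (8.02 ± 0.39), miR-148a-3p (7.59 ± 1.00), miR-10400-5p (7.58 ± 0.40) and miR-375-3p (7.47), a miRNA of pancreatic islets and glandular epithelium. The leading piRNAs were piR-hsa-736338 (11.95 ± 0.82), piR-hsa-47220 (11.63 ± 0.52), piR-hsa-2852822 (11.62 ± 0.53) and piR-hsa-76242 (11.43 ± 1.15). Among tRNAs, tRNA-Glu-TTC-2-1 and tRNA-Glu-TTC-2-2 shared identical values (10.96 ± 0.65), as did tRNA-Lys-CTT-1-1 and tRNA-Lys-CTT-1-2 (9.91 ± 1.55). The deposited values were scaled to an effective library size of which each class made up only a part. That size differed by class, with medians of 10.65 (miRNAs), 10.162 (piRNAs) and 8.756 (tRNAs) in units of 1e6 reads. Levels of different classes were not compared here.

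Monthly sampling of the same participants asks whether sperm small RNA drifted over the 6 study months. No miRNA, piRNA or tRNA passed the test between months. The miRNA with the smallest p was miR-1976 (chromosome 1, 26554542 to 26554593), whose level in month 9 was 0.47 ± 0.17 log2 (SE, n = 28 and 30 libraries) above that in month 4. It was followed by miR-4448, with a difference of -0.54 ± 0.22, and by miR-146b-5p, a miRNA induced in inflammation, with 0.24 ± 0.18. Among tRNAs, tRNA-Gly-CCC-3-1 differed by 0.45 ± 0.13, tRNA-Val-CAC-3-1 by 0.25 ± 0.11 and tRNA-Met-CAT-7-1 by 0.065 ± 0.17. Among piRNAs the smallest p belonged to piR-hsa-768712, which differed by -0.13 ± 0.19, followed by piR-hsa-47765 with 0.15 ± 0.18 and piR-hsa-2830281 with 0.11 ± 0.11.

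With limma, 0 miRNAs, 0 piRNAs and 0 tRNAs had an adjusted p under 0.05 between the 6 months, and limma with voom weights also gave 0 in each class. At an unadjusted p under 0.05 there were 13 miRNAs, 44 piRNAs and 2 tRNAs, where chance alone gives 16.9, 93.2 and 5.4. The adjusted p of miR-1976 was 0.538, that of miR-4448 and miR-146b-5p 0.883, that of the 3 piRNAs 0.976, and that of tRNA-Gly-CCC-3-1 and tRNA-Val-CAC-3-1 0.333. A straight trend over the months was likewise found by limma in 0 features of each class, and by voom in 0 (unadjusted p under 0.05 in 8 miRNAs, 68 piRNAs and 5 tRNAs). The slope of miR-1976 was 0.10 ± 0.028 log2 per month (SE), with an adjusted p of 0.122. Month 9 against month 4 gave 0 calls in each class with limma and with voom (unadjusted p under 0.05 in 9 miRNAs, 94 piRNAs and 2 tRNAs). The median absolute difference was 0.098 log2 for miRNAs, 0.093 for piRNAs and 0.093 for tRNAs, against median SEs of 0.16, 0.15 and 0.14. The 95% interval of the difference lay within 1 log2 of 0 for 98.2% of miRNAs, 98.3% of piRNAs and 100% of tRNAs. The call changed for miR-1976 in the trend with quantile normalization (adjusted p = 0.0304 by limma), with array weights (0.0213) and without the shallow libraries, the last chosen after the data were seen (0.02), where it was called between months too (0.0477). It also changed for tRNA-Gly-CCC-3-1 in month 9 against month 4 without batch 1 (adjusted p = 0.00869, 0.60 log2) and with depth as a covariate, chosen after the data were seen (0.0474). Over the alternatives the adjusted p ran from 0.02 to 0.549 for the trend of miR-1976, from 0.0477 to 1 for its month differences and from 0.00869 to 0.997 for tRNA-Gly-CCC-3-1.

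Among lists of related RNAs fixed beforehand, tRNA-Gly was called for a rise over the months, but not under its 2 alternatives. Of its 10 genes 8 had a slope above 0, but 2 pairs of the 8 hold identical values and count in full in the test. The highest slopes were those of tRNA-Gly-CCC-3-1 (0.053 log2 per month), tRNA-Gly-CCC-1-1 (0.044) and tRNA-Gly-GCC-5-1 (0.038). The mean slope of all 10 was 0.023 log2 per month (camera, adjusted p = 0.0223 over 6 tRNA lists). The call was lost with median-centred values (adjusted p = 0.0775), and adjusted p = 0.397 with an estimated correlation. By fry, which asks whether the genes of a list move 1 way on balance, the adjusted p was 0.565. No member of tRNA-Gly passed alone, with 0 of 10 adjusted over the list alone and 0 over all tRNAs. The mean slope of tRNA-Ala was about the same, 0.022. The other 5 tRNA lists had adjusted p from 0.135 (tRNA-Ala) to 0.675 (tRNA-Val). None of the 11 miRNA lists passed, with adjusted p from 0.113 for leukocyte markers to 0.916 for the let-7 family. In every list, 0 members had a slope past the test, adjusted over the list alone or over all features.

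Repeated samples also measure how far participants differ from each other and how far each varies from month to month. Small RNA levels differed between participants of the same batch for most features of all 3 classes. Among miRNAs the highest share of variance between participants was that of miR-10b-5p. It was followed by miR-486-5p, an erythroid miRNA of the ANK1 locus, by miR-4699-5p, and by miR-3150b-5p. Further on came miR-320a-3p and miR-320b, made without Drosha processing, miR-4699-3p between them, and miR-891a-5p, an X-linked miRNA enriched in the epididymis (chromosome X, 146027794 to 146027872). At the other end, let-7e-5p, miR-6796-3p, miR-7107-5p and miR-183-5p varied within a participant far more than between participants, with SDs within of 0.76, 0.58, 0.69 and 0.64 log2 against 0.0, 0.088, 0.11 and 0.11 between.

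Of the miRNAs, 310 of 338 (91.7%) differed between participants within batches by limma at an adjusted p under 0.05, as did 1691 of 1863 piRNAs (90.8%) and 100 of 107 tRNAs (93.5%). The intraclass correlation, the share of the variance that lies between participants of a batch, had a median of 0.289 for miRNAs, 0.271 for piRNAs and 0.371 for tRNAs. Its SD over resampled participants was 0.0315, 0.0273 and 0.0416. It was 0.79 for miR-10b-5p, 0.776 for miR-486-5p and 0.763 and 0.729 for miR-4699-5p and miR-4699-3p. It was 0.755 for miR-3150b-5p, 0.737 for miR-320a-3p, 0.726 for miR-320b and 0.723 for miR-891a-5p. For let-7e-5p it was -0.0475, and for miR-6796-3p, miR-7107-5p and miR-183-5p 0.0228, 0.0266 and 0.0298. The highest piRNAs were piR-hsa-48970 (0.893), piR-hsa-153355 (0.886) and piR-hsa-3701953 (0.824), and the lowest were piR-hsa-82017 (-0.0787) and piR-hsa-675870 (-0.0596). Among tRNAs, tRNA-Ile-AAT-6-1 reached 0.78, and tRNA-Met-CAT-3-1 and tRNA-Met-CAT-3-2, with identical values, 0.707. The lowest were tRNA-Ala-AGC-4-1 (0.00561) and tRNA-Gly-GCC-4-1 (0.0406). An intraclass correlation over 0.5 was found for 57 miRNAs (16.9%), 268 piRNAs (14.4%) and 26 tRNAs (24.3%). The median SD within a participant was 0.60 log2 for miRNAs, 0.59 for piRNAs and 0.53 for tRNAs, against 0.37, 0.32 and 0.39 between participants.

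**Figure D1:**
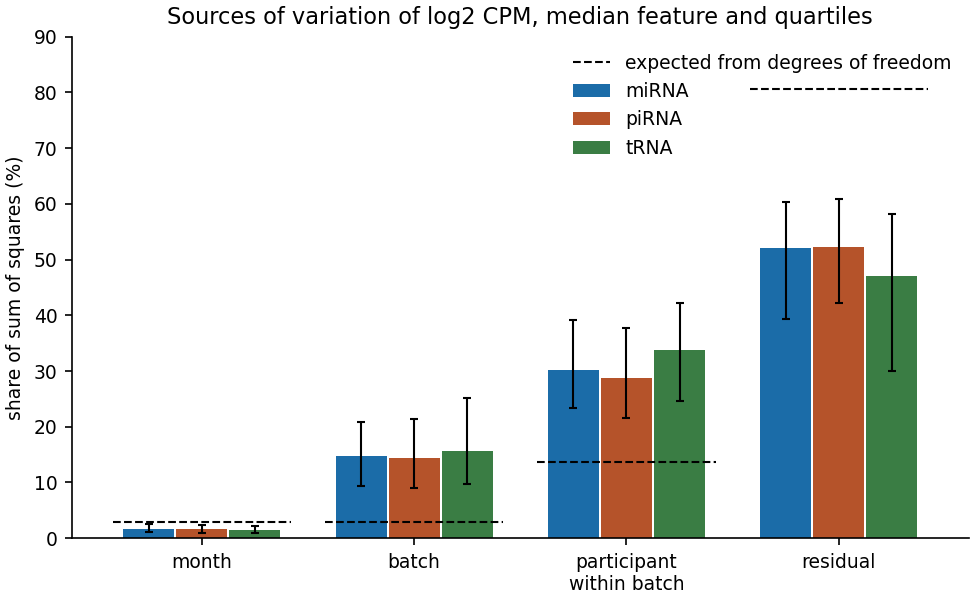
Share of the sum of squares of log2 CPM (%) taken by month, batch, participant within batch and residual, as the median feature of each class, with bars to the quartiles and a dashed line at the share that the degrees of freedom alone give. Month took a median of 1.69% for miRNAs, under the 2.86% that its degrees of freedom give, and participants took 30.1% against 13.7%.

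**Figure D2:**
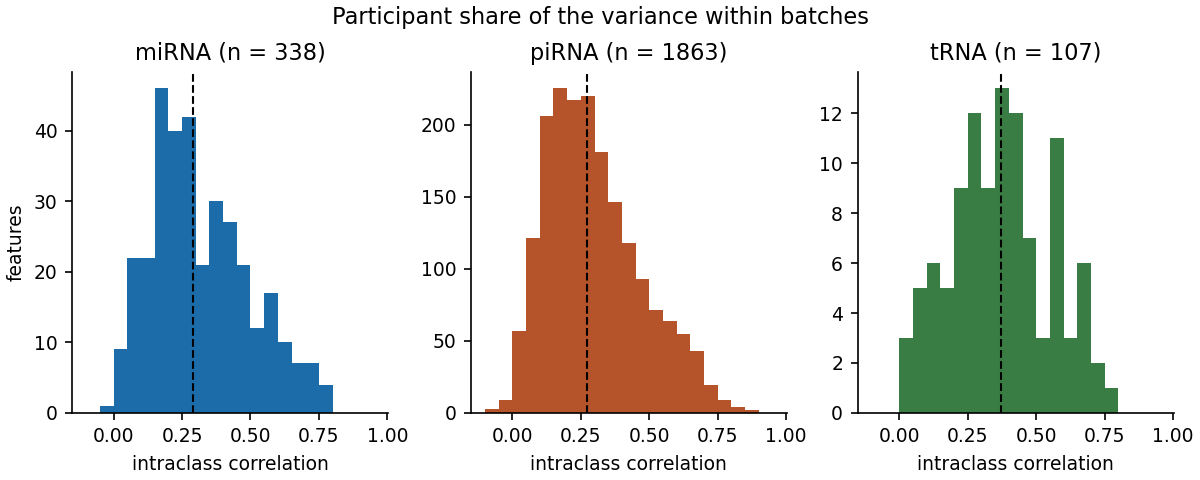
Number of features by intraclass correlation within batches for 338 miRNAs, 1863 piRNAs and 107 tRNAs, with a dashed line at the median. The medians were 0.289, 0.271 and 0.371, and each class held features near 0 and features above 0.7.

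Markers of other cells that a semen sample can hold were among the features that differed between participants. All 7 measured leukocyte markers and all 5 measured erythrocyte markers passed, as did 9 of 11 epithelial markers, with the same counts adjusted over the list alone. The leukocyte list also held miR-223, miR-142 and miR-146a, and the erythrocyte list miR-451a and miR-144. None of these was among the features measured, nor was miR-96 of the epithelial list. The counts therefore rest on the remaining markers, some of which stand in other lists too. Of all miRNAs 91.7% passed, so these counts do not set the lists apart. Epithelial markers had a median intraclass correlation of 0.564 against 0.336 in lists of the same size and abundance drawn at random, with miR-182-5p at 0.707, miR-141-3p at 0.643 and miR-205-5p at 0.635. Erythrocyte markers had 0.642 against 0.384, led by miR-486-5p. Neither passed after adjustment over the 11 miRNA lists (permutation p = 0.0138 and adjusted p = 0.152 for epithelial markers, p = 0.0432 and adjusted p = 0.238 for erythrocyte markers). The medians of the remaining miRNA lists ran from 0.268 for the let-7 family to 0.559 for the miR-888 cluster, and those of the tRNA lists from 0.312 for tRNA-Ala to 0.525 for tRNA-Glu. Their adjusted permutation p lay between 0.433 and 0.981.

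Batch was compared over the means of participants, which are its replicates. The strongest difference among miRNAs was that of miR-127-3p, an imprinted miRNA of the DLK1-DIO3 region (chromosome 14, 100882979 to 100883075), which was lowest in batch 2 and highest in batch 4. miR-3182 was highest in batch 1, and miR-6826-3p was highest in batch 5. miR-1247-3p, miR-4781-5p and miR-4712-3p also differed. Among piRNAs, piR-hsa-794864 and piR-hsa-788431 were both lowest in batch 3 and highest in batch 5, and piR-hsa-728602 was lowest in batch 2. The tRNA genes tRNA-Val-CAC-2-1 and tRNA-Lys-CTT-1-1 stood apart by about as many log2 units.

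Mean log2 CPM of miR-127-3p ran from 1.73 in batch 2 to 3.99 in batch 4 (pooled SD between participants 0.33, n = 5 a batch, limma adjusted p = 2.39e-07). For miR-3182 the means ran from 2.33 in batch 5 to 4.60 in batch 1 (adjusted p = 0.000106), and for miR-6826-3p from 4.01 in batch 2 to 5.57 in batch 5 (adjusted p = 0.00131). The ranges between batches were 2.42 log2 for miR-1247-3p, 1.45 for miR-4781-5p and 1.35 for miR-4712-3p. The piRNA piR-hsa-794864 ran from 1.90 to 5.39 and piR-hsa-788431 from 0.73 to 4.17 (limma adjusted p = 2.13e-14 for each). That of piR-hsa-728602 ran from -0.30 in batch 2 to 3.72 in batch 5. The tRNA tRNA-Val-CAC-2-1 had 4.99 in batch 5 and 7.88 in batch 1 (limma adjusted p = 7.86e-08). Both tRNA-Lys-CTT-1-1 and tRNA-Lys-CTT-1-2 had 8.10 in batch 4 and 11.42 in batch 3 (adjusted p = 5.36e-07). In all, 95 miRNAs (28.1%), 601 piRNAs (32.3%) and 37 tRNAs (34.6%) differed between batches at an adjusted p under 0.05, with median ranges of 1.32, 1.13 and 1.27 log2. With 1 participant left out in turn the counts ran from 55 to 127 miRNAs, 488 to 648 piRNAs and 29 to 43 tRNAs. Because each batch held other participants, a batch and its participants cannot be told apart beyond this comparison. With the depth of each library as a covariate, chosen after the data were seen, the counts fell to 26 miRNAs, 440 piRNAs and 21 tRNAs.

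**Figure D3:**
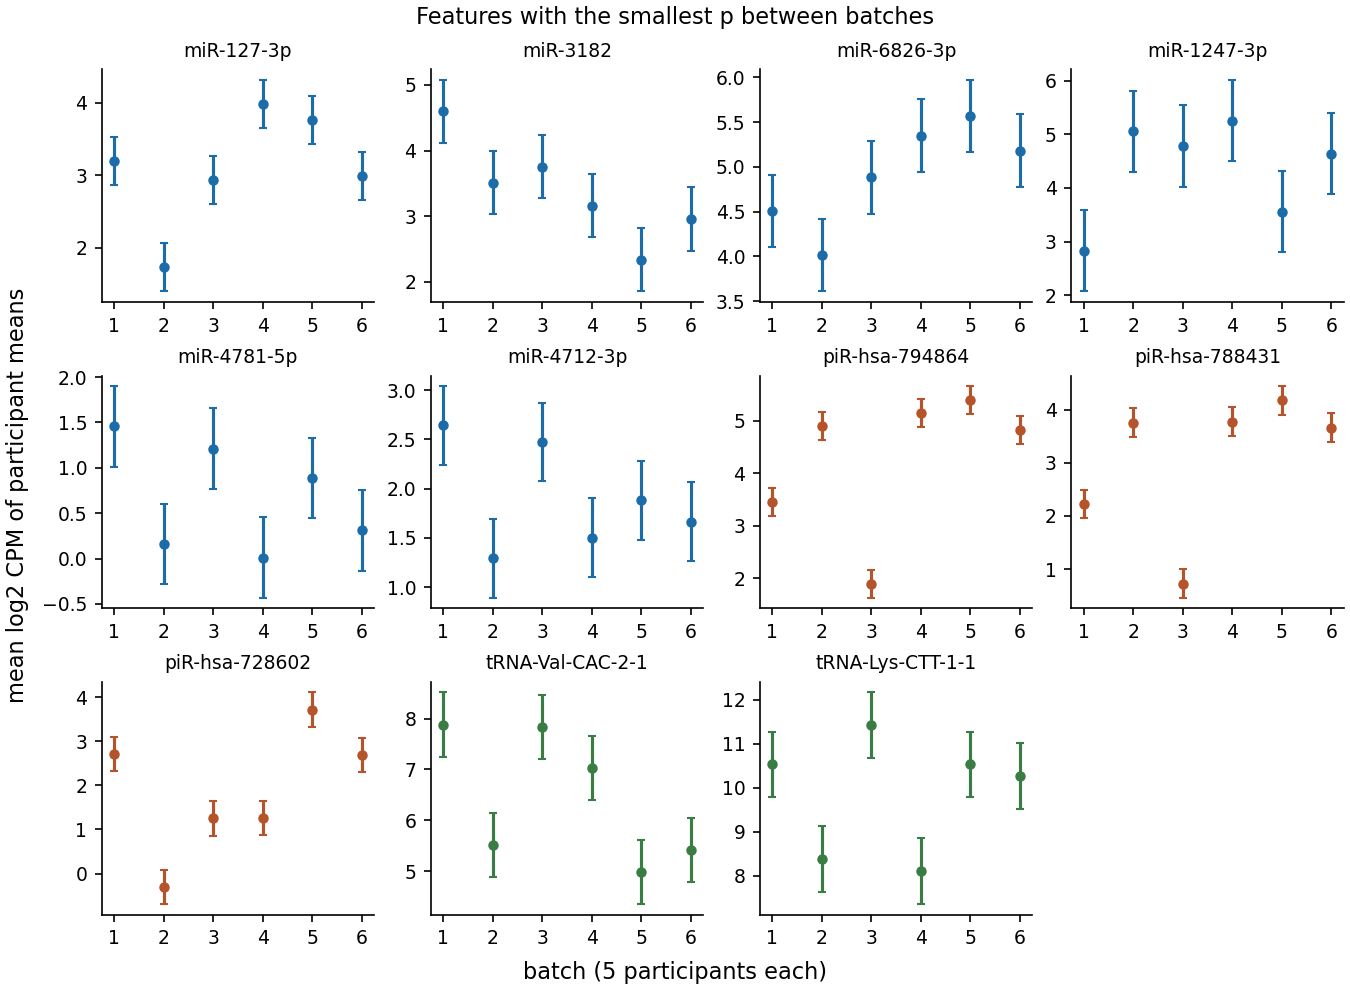
Mean log2 CPM of participant means in each of the 6 batches (points, 5 participants each) for the features with the smallest p, with bars of 1 pooled SD between the participants of a batch, and with tRNA-Lys-CTT-1-2, identical to tRNA-Lys-CTT-1-1, left out. The means of miR-127-3p ran from 1.73 in batch 2 to 3.99 in batch 4.

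Of the epithelial markers, 7 of 11 differed between batches over all miRNAs and 7 adjusted over the list alone, and lists were not compared with each other in this. Of all miRNAs 28.1% differed and of all tRNAs 34.6%, and no list was tested against that share. Among them miR-375-3p averaged 8.17 and 8.70 in the shallower batches 2 and 4, and 6.82 to 7.30 in the others. Of the let-7 family, 3 of 8 members differed (4 adjusted over the list alone), with let-7b-5p spanning 1.49 log2 and let-7a-5p 1.16. Of the family of miR-34 and miR-449, 3 of 5 differed (4 over the list alone), including miR-34c-5p, a miRNA of the male germline that ranged from 5.85 in batch 4 to 7.16 in batch 1. The miR-888 cluster had 0 of 3 by limma and 0 over the list alone. Among tRNAs all 4 tRNA-Glu genes differed, as did 5 of 10 tRNA-Gly, 5 of 10 tRNA-Val and 6 of 13 tRNA-Lys genes, with the same counts adjusted over the list alone. Genes with identical values are each counted here, namely 2 pairs of tRNA-Glu, 1 of tRNA-Gly and 1 of tRNA-Lys among those that differed.

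Whether the months ran differently in different batches was tested as an interaction of 25 terms. The smallest p among the miRNAs named here was that of let-7c-5p (p = 0.00517 and adjusted p = 0.35, both by limma). By limma, 0 miRNAs, 0 piRNAs and 0 tRNAs passed, and with voom weights also 0 in each class (unadjusted p under 0.05 in 21 miRNAs, 109 piRNAs and 8 tRNAs). The smallest adjusted p was 0.35 for miRNAs, 0.0884 for piRNAs and 0.0932 for tRNAs. With participant as a random effect, piR-hsa-2832094 (adjusted p = 0.0157) and tRNA-Gly-GCC-5-1 (adjusted p = 0.0323) passed, and 1 or 2 features also passed without batch 2, without batch 3 or with only the participants with all 6 months. Array weights gave 66 miRNAs, 524 piRNAs and 50 tRNAs, and with the same weights 10 shuffles of participants among batches gave up to 58, 839 and 43. Only the piRNA count lay within its shuffles. The shuffled counts were large in all 3 classes, and 10 shuffles are too few to test the miRNA and tRNA counts. In simulated data a change of 2 log2 in 1 batch was called for 50% of miRNAs, 50% of piRNAs and 62.5% of tRNAs, and a change of 1 log2 for 0%, 16.4% and 22.2%, so most changes of 1 log2 in 1 batch would be missed.

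The series title names coordination of small RNA networks, which was measured here as shared variation from month to month within participants. In each class the features varied along a common axis, the first principal component of the values after participant and month means were removed. At its upper end among miRNAs stood miR-4763-5p, miR-638, miR-6511a-5p, miR-6803-5p and miR-34c-5p, the germline miRNA (chromosome 11, 111513439 to 111513515). At its lower end stood miR-375-3p (chromosome 2, 219001645 to 219001708), miR-339-3p, miR-1247-3p, let-7c-5p and miR-148a-3p (chromosome 7, 25949919 to 25949986). When the miRNA axis was high in a library, the piRNA axis was high and the tRNA axis low in that library, in every batch. The sign of each axis is a convention, so this does not mean that tRNAs fell as miRNAs rose. A high miRNA axis went with a lower log2 CPM of the miRNA class (r = -0.625). A low tRNA axis went with a higher log2 CPM of the tRNA class (r = -0.761). The class CPM is summed over the same features as the axis, so it is not a separate measure. On the tRNA axis, tRNA-Asn-GTT-3-1, tRNA-Thr-CGT-2-1 and tRNA-Thr-TGT-2-1 stood at the upper end, and tRNA-Gly-TCC-1-1, tRNA-Gly-CCC-1-1 and tRNA-Cys-GCA-11-1 at the lower end.

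The axis took 20.9% of the within-participant variance of miRNAs (SD over resampled participants 2.31), 22.8% of that of piRNAs (1.67) and 26.6% of that of tRNAs (2.62). In 1000 shuffles of each feature within participants the highest shares were 4.49%, 3.36% and 4.57% (permutation p = 0.001 in each class, the smallest that the shuffles can give). The correlation with the miRNA axis was 0.902 for miR-4763-5p, 0.857 for miR-638, 0.787 for miR-34c-5p, -0.784 for miR-375-3p and -0.76 for let-7c-5p and miR-148a-3p. It was 0.80 for miR-6511a-5p, 0.789 for miR-6803-5p, -0.778 for miR-339-3p and -0.764 for miR-1247-3p. On the piRNA axis, piR-hsa-1236009 had 0.937, and piR-hsa-2843704, piR-hsa-168567, piR-hsa-2866944 and piR-hsa-973644 had 0.905 to 0.90. At its other end piR-hsa-186960 and piR-hsa-2859990 had -0.928, piR-hsa-1314938 -0.926, piR-hsa-179556 -0.923 and piR-hsa-7459908 -0.91. On the tRNA axis, tRNA-Asn-GTT-3-1 had 0.893, tRNA-Thr-CGT-2-1 0.871, tRNA-Thr-TGT-2-1 0.858, tRNA-Asp-GTC-1-1 0.85 and tRNA-Ala-AGC-6-1 0.841. The lower end held tRNA-Gly-TCC-1-1 (-0.867), tRNA-Arg-CCG-2-1 (-0.833), tRNA-Gly-CCC-1-1 and tRNA-Gly-CCC-1-2 (-0.829) and tRNA-Cys-GCA-11-1 (-0.808). The sign of tRNA-Arg-CCG-2-1 turned to 0.329 when reads were thinned to 1 depth, a setting chosen after the data were seen.

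Between classes, the miRNA and piRNA axes had a Pearson r of 0.912 and a Spearman rho of 0.892 over all libraries. The miRNA and tRNA axes had -0.874 and -0.873, and the piRNA and tRNA axes had -0.89 and -0.881. All 6 permutation p within participants were 1e-05, the smallest that 100000 permutations can give, and 1e-05 after adjustment over the 3 pairs. Within single batches r ran from 0.836 to 0.957 for miRNA and piRNA, from -0.938 to -0.758 for miRNA and tRNA and from -0.948 to -0.86 for piRNA and tRNA. Without the 2 libraries farthest from the median r was 0.909, -0.884 and -0.877, and the pooled sign was found in 30 of 30 participants for each pair. With depth as a covariate the miRNA and piRNA axes had r = 0.562, and the axis took 13.1% of the miRNA variance.

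**Figure D4:**
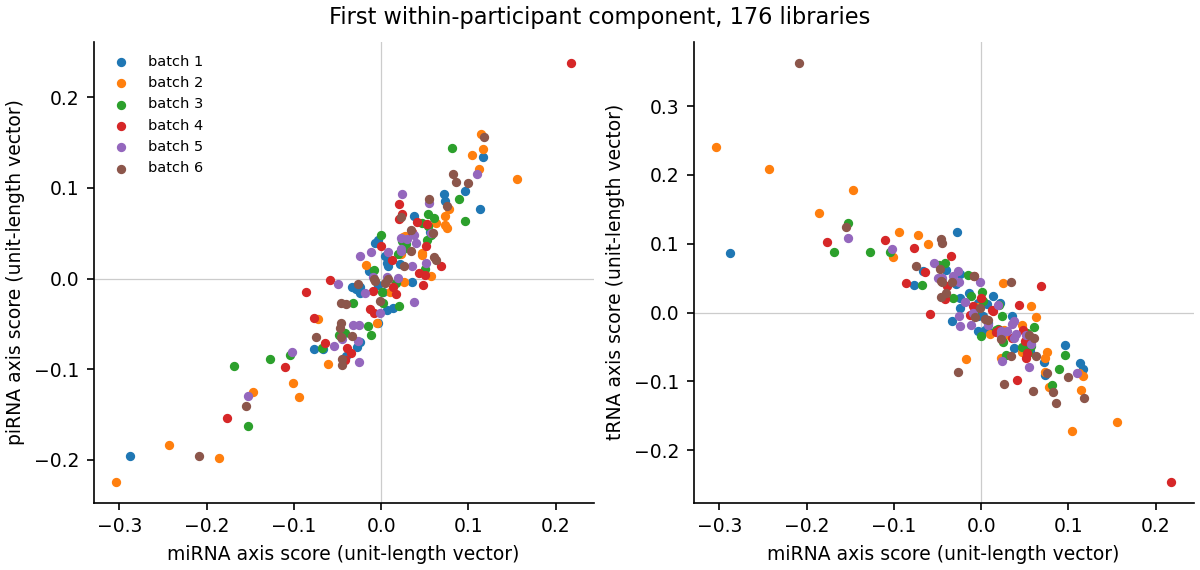
Score of each library on the within-participant axis of piRNAs (left) and of tRNAs (right) against its score on that of miRNAs, as entries of unit-length vectors, coloured by batch. The piRNA score rose with the miRNA score (r = 0.912) and the tRNA score fell with it (r = -0.874). The sign of each axis is a convention and gives no direction of tRNA levels against miRNA levels.

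The axes followed the depth of the libraries within participants. Each was compared with the effective library size, the reads of the 3 classes and the abundance of its class in CPM, 9 relations in all, each over all libraries. The class CPM is summed over the same features as the axis. Its relation with the axis is that of a whole with its parts and no separate evidence. The miRNA axis had r = 0.778 and rho = 0.752 with the log2 effective library size, the piRNA axis 0.736 and 0.685, and the tRNA axis -0.568 and -0.563. Against the log2 reads of the 3 classes the values of r were 0.786, 0.717 and -0.742, and those of rho 0.749, 0.679 and -0.754. Against the log2 CPM of the class, r was -0.625 for miRNAs and -0.761 for tRNAs, with rho of -0.596 and -0.746. The permutation p of these relations was 1e-05 for r and for rho, the smallest possible, and 1.1e-05 after adjustment. For piRNAs the relation with the class CPM was weaker, with r = -0.319 (permutation p = 0.002, also after adjustment) and rho = -0.159 (permutation p = 0.065). It ranged from -0.8 to 0.158 over the batches, so that it did not hold in each. In single batches the miRNA axis had r from 0.683 to 0.898 with library size, the piRNA axis from 0.529 to 0.9 and the tRNA axis from -0.798 to -0.298. Without the 2 libraries farthest from the median r with library size was 0.796, 0.753 and -0.607. With the reads of the 3 classes r ran over batches from 0.686 to 0.899, from 0.52 to 0.879 and from -0.954 to -0.537, and without the 2 farthest libraries it was 0.802, 0.737 and -0.812. With the class CPM it ran from -0.86 to -0.319 for miRNAs and from -0.856 to -0.601 for tRNAs, and without the 2 farthest it was -0.6, -0.237 and -0.735.

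Within the miRNA axis the let-7 family, tumour suppressor miRNAs controlled by LIN28, lay low as a group. Its 8 members had a median correlation of -0.438 with the axis against 0.288 in matched random lists (permutation p = 0.0012, adjusted p = 0.0132), led by let-7c-5p (-0.76), let-7a-5p (-0.757) and let-7f-5p (-0.589). The members vary together, with a mean pairwise r of 0.409 against 0.055 in random lists. The permutation takes them as separate, so its p may be too small. The family of miR-34 and miR-449 lay high, with a median of 0.605 against 0.247, without passing (permutation p = 0.125, adjusted p = 0.275). Epithelial markers had a median of -0.346 against 0.216 (permutation p = 0.0532, adjusted p = 0.214), with miR-429 at -0.745 and miR-200c-3p at -0.673. Of the 11 epithelial markers 7 lay below 0, as did 36.7% of all miRNAs. The others lay above 0, with miR-31-5p at 0.441 and miR-182-5p at 0.378. Leukocyte markers had a median of 0.123 (adjusted permutation p = 0.87) and erythrocyte markers one of -0.18 (adjusted permutation p = 0.805). The medians of the other lists were -0.529 for the miR-29 family, -0.276 for the group of miR-10, miR-99, miR-100 and miR-125, 0.27 for the miR-17-92 clusters, 0.147 for the miR-30 family, 0.000509 for the miR-888 cluster and 0.259 for miRNAs of the paternal stress literature. Their adjusted p ran from 0.214 to 0.98. On the tRNA axis the medians ran from -0.526 for tRNA-Glu to 0.501 for tRNA-Ala, with adjusted permutation p from 0.483 to 0.854.

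**Figure D5:**
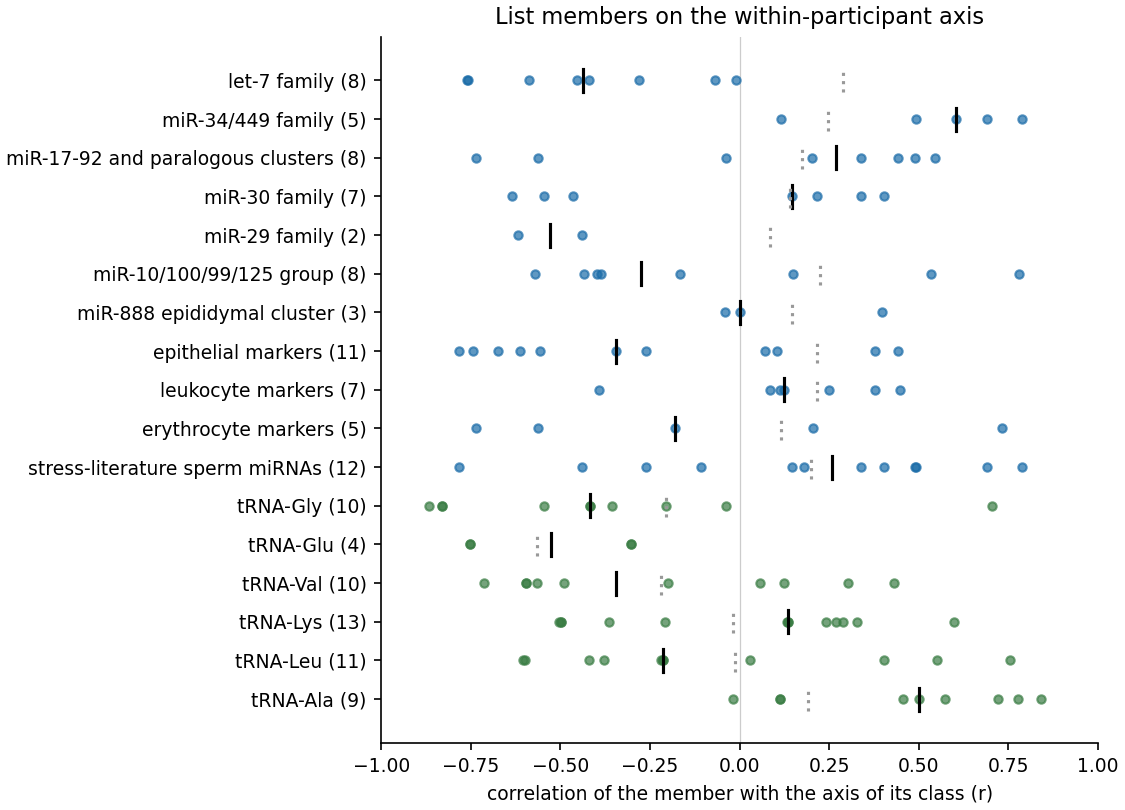
Correlation of each member of a list (points, number of members in brackets) with the within-participant axis of its class, with the median of the list as a solid bar and that of matched random lists as a dotted bar. The let-7 family had a median of -0.438 against 0.288 in random lists.

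Members of several families also rose and fell together from month to month. The random lists used here were matched on size and mean level, not on sequence. Whether members of similar sequence share reads was not tested. The mean pairwise correlation within participants was 0.409 in the let-7 family against 0.055 in matched random lists (permutation p = 0.0002, adjusted p = 0.0022). It was 0.559 against 0.0149 among miR-888-5p, miR-891a-5p and miR-892a of the epididymal miR-888 cluster on chromosome X (permutation p = 0.0026, adjusted p = 0.0143). These were 2 of 11 miRNA lists. The other 9 had means of 0.112 for erythrocyte markers to 0.531 for the miR-29 family, with adjusted permutation p from 0.0627 to 0.449. Among tRNAs, 5 of 6 isotypes passed. Their means were 0.214 for tRNA-Gly (adjusted permutation p = 0.0148), 0.807 for tRNA-Glu (0.019), 0.283 for tRNA-Val (0.0084), 0.197 for tRNA-Leu (0.0148) and 0.274 for tRNA-Ala (0.0168), with 0.0947 for tRNA-Lys (0.096). Pairs of tRNA genes with identical values count toward these means. With such genes counted once, chosen after the data were seen, only tRNA-Val and tRNA-Leu passed, each with an adjusted permutation p of 0.0396. After the axis was removed 7 miRNA lists passed, among them the miR-30 family, the miR-17-92 clusters and epithelial markers, each with an adjusted permutation p of 0.00396, while tRNA-Gly (0.12) and tRNA-Ala (0.519) no longer did. With median-centred values 5 miRNA lists and 2 tRNA lists passed.

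Coordination was also measured inside each of the 27 participants with all 6 months, as the mean absolute correlation of all pairs of features over the months. It had a median of 0.441 for miRNAs, 0.47 for piRNAs and 0.458 for tRNAs, against 0.375 for months shuffled feature by feature. All 27 participants lay above each of their 20 shuffles in every class. Depth was not removed here, and the shuffles also break whatever depth does to a whole library. The comparison therefore cannot separate coordination from depth. The values ran from 0.398 to 0.572 for miRNAs, from 0.391 to 0.55 for piRNAs and from 0.396 to 0.65 for tRNAs, and participants were not grouped by them.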

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

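Of the tests reported here, those of other cells, of depth for piRNA and tRNA batches and of the axis of miRNA and piRNA alone were chosen after the result was seen, as were depth as a covariate and thinned reads.

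In 3 of the 66 groups of 5 participants of a batch that were examined for the features named by batch, 1 participant mean stood apart from the other 4 by more than Dixon's limit for 5 values. Chance gives about 1 in 20 groups, or 3.3 of 66, so this is about as many as chance alone would give. For miR-1247-3p the lowest mean of batch 3 was 3.45 log2 CPM against 4.87 to 5.30 in the other 4 participants, a gap of 0.766 of the range. For piR-hsa-788431 the lowest mean of batch 1 was 1.58 against 2.23 to 2.46 (0.735 of the range). For tRNA-Lys-CTT-1-1 the highest mean of batch 5 was 11.81 against 10.05 to 10.31 (0.855 of the range).

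Regrouping of the samples was tested with 100 splits for each count, the real split included. With participants shuffled within batch and month, chance can be excluded for the differences between participants, since only 1 split, the real one, reached 310 miRNAs (highest other 40), 1691 piRNAs (368) and 100 tRNAs (20). With participants shuffled among batches, chance can be excluded for the differences between batches in the same way, with 95 miRNAs against a highest other of 1, 601 piRNAs against 2 and 37 tRNAs against 7. For the months and the interaction the real count was 0 in each class, which all 100 splits reach by construction, so that the splits say nothing about them and exclude nothing. The highest other splits gave 16 miRNAs, 7 piRNAs and 2 tRNAs for month differences, 2, 2 and 3 for the trend, and 2, 21 and 2 for month 9 against month 4. For the interaction they gave 28 miRNAs, 1 piRNA and 2 tRNAs. Single splits with that many calls may come from a structure of the samples or from features that vary together, which was not tested.

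The axis that the 3 classes share within participants follows library depth, so counting noise and the constant under the logarithm were weighed first. When reads were thinned to 1 number per library, the new axis had an absolute r of at least 0.844 with the deposited axis for miRNAs and piRNAs, against the 0.8 set for excluding depth, which argues against counting noise as the whole of that part. Depth as a covariate took the miRNA share of the axis from 20.9% to 13.1% and the r of the miRNA and piRNA axes from 0.912 to 0.562, so depth stays open as part of it. For all 3 classes the lowest absolute r was 0.703, that of tRNAs, between the 2 limits set, so by these limits depth cannot be told apart for tRNAs. The tRNA axis took 28% of the variance with thinned reads and 22.8% with depth as a covariate, against 26.6% as designed. Its r with the miRNA axis was then -0.675 and -0.684, against -0.874. An axis thus remained in tRNAs under both settings. The share after thinning does not show that it was the same axis. The covariate removes only a straight-line relation with the tRNA library size. Depth therefore stays open for the tRNA axis. A GC trend of the hairpins does not account for the miRNA axis. Its share of the variance of 324 miRNAs was 19.9% after that trend was removed from each library and 21.0% before. Still, miRNAs of higher GC lay higher on it (r = 0.279, permutation p = 2e-05 across miRNAs, which are not independent replicates). GC was taken from the hairpin or its side, not from the sequenced RNA, and GC of piRNAs and tRNAs was not examined. A varying share of RNA from other cells, which isolation of sperm is meant to remove, may contribute and stays open, since epithelial and leukocyte markers differed in their median correlation with the axis by -0.469 with a permutation p of 0.198. No explanation in the sperm themselves was tested, because the design gives no group for it.

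Differences between batches were weighed against depth, since batches 2 and 4 were shallower. With depth as a covariate 26 of the 95 miRNAs remained, all of them among the 95, under the 1 in 3 set as the limit, so depth may account for part of the miRNA differences. The fall in the count does not show how much, since miR-4712-3p and miR-4781-5p lost their call at ranges of 0.985 and 0.841 log2 (adjusted p 0.0572 and 0.0518), against 1.35 and 1.45 without the covariate. For piRNAs 440 features passed, 407 of them among the 601, above the 2 in 3 set as the limit, which argues against depth as the whole cause. For tRNAs 21 passed, all among the 37, and depth cannot be told apart. What the participants of a batch had in common stays open as well, untested, because each batch held other participants. Differences between participants largely kept their call with the covariate, in 305 of the 310 miRNAs, 1623 of the 1691 piRNAs and 96 of the 100 tRNAs. This argues against stable depth differences as the whole cause. The median intraclass correlation for miRNAs was 0.302 with the covariate and 0.289 without. The covariate can lower the variance within participants as well as between them, so this ratio does not show how much depth adds.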

How the results depend on the processing

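The alternatives with depth as a covariate, without the shallow libraries, with identical features counted once, with voom weights and with thinned reads were chosen after the results were seen. Of the values that answer a comparison, 483 stayed the same under an alternative, 27 moved by more than their spread, 18 became stronger and 15 weaker. Among values of single features and lists together 1424 stayed the same, 113 moved, 10 became stronger, 12 weaker and 1 reversed. A count was taken as the same within a set factor of its main value, and a count of 0 that stayed 0 as the same. The 483 thus include the empty counts of the months and the interaction. They also include batch counts with 1 participant left out, so they are not a measure of robustness by themselves. An r between axes was taken as the same if its sign and a permutation p under 0.05 were kept, whatever its size. The r of the miRNA and piRNA axes is thus among the 483 at 0.562 with depth as a covariate, against 0.912 as designed. The r of the axes kept its sign under all 15 alternatives, from 0.562 to 0.934 for miRNAs and piRNAs, from -0.922 to -0.675 for miRNAs and tRNAs and from -0.943 to -0.651 for piRNAs and tRNAs. With 1 participant left out in turn, 55 to 127 miRNAs, 488 to 648 piRNAs and 29 to 43 tRNAs differed between batches. Depth left up to 81 miRNAs, 368 piRNAs and 18 tRNAs of a library without a read, and a change confined to 1 batch was called for only 50% of miRNAs at 2 log2 in simulated data.

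With only features at or above the class median, which leaves fewer features to test, 168 miRNAs, 915 piRNAs and 54 tRNAs differed between participants, and 297 piRNAs and 12 tRNAs between batches. The median intraclass correlation was then 0.379, 0.323 and 0.473, and the axis share 26.2%, 26.9% and 29.6%. The cause was not tested for any of the changes that follow. Participant as a random effect gave an interaction in 1 piRNA (piR-hsa-2832094, adjusted p 0.0157, range over alternatives 0.0157 to 0.875) and 1 tRNA (tRNA-Gly-GCC-5-1, 0.026 to 1). Median centring gave axis shares of 26.4% for piRNAs and 32.9% for tRNAs, a trend in 0 tRNA lists, and co-variation in 5 miRNA lists and 2 tRNA lists. Quantile normalization gave a trend in 1 miRNA (miR-1976, 0.02 to 0.549 over alternatives), an intraclass correlation of 0.329 for miRNAs, and axis shares of 24.9% for piRNAs and 23.5% for tRNAs. Participants with all 6 months gave 24 tRNAs between batches and an interaction in 1 tRNA. Array weights gave a trend in 1 miRNA, 191 miRNAs, 958 piRNAs and 63 tRNAs between batches, and an interaction in 66, 524 and 50.

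Without batch 2 the miRNA intraclass correlation was 0.321 and the axis share 18.3%, and 2 tRNAs had an interaction. Without batch 3, 1 piRNA had one, and without batch 6 the piRNA intraclass correlation was 0.3. Ranks gave 0.336 for miRNAs and 0.301 for piRNAs, and with batch not removed the 3 classes had 0.36, 0.357 and 0.422. With depth as a covariate 26 miRNAs and 21 tRNAs differed between batches, the axis shares were 13.1%, 18.7% and 22.8%, and 1 tRNA differed between month 9 and month 4 (tRNA-Gly-CCC-3-1). Without the shallow libraries 1 miRNA (miR-1976) differed between months and 1 had a trend, the intraclass correlations were 0.375, 0.312 and 0.437, and the piRNA axis share was 26.7%. Thinned reads gave a piRNA share of 18.4% and turned the correlation of tRNA-Arg-CCG-2-1 with the tRNA axis to 0.329. Removal of the axis left co-variation in 7 miRNA lists and 3 tRNA lists, the estimated correlation left a trend in 0 tRNA lists, and identical features counted once left co-variation in 2 tRNA lists.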

Other observations

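The test of the complementary stretch of the hairpins was chosen after the result was seen, as were the miRNAs named in the next paragraph.

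Members of 1 genomic cluster differed widely in how far they separated participants. Of the epithelial cluster of miR-182 and miR-183, on chromosome 7, miR-182-5p had an intraclass correlation of 0.707 at a mean of 6.05 log2 CPM, and miR-183-5p one of 0.0298 at 2.50. The difference between them was not tested. Among leukocyte markers, miR-150-5p of mature lymphocytes had 0.567 at a mean of 1.09 log2 CPM, miR-155-5p of activated lymphocytes 0.545 at 1.12 and miR-181a-5p 0.462 at 3.10. Among erythrocyte markers, miR-486-5p and miR-486-3p had 0.776 and 0.644 and miR-363-3p 0.642, while miR-16-5p, which most tissues express, had 0.395. All 3 measured members of the miR-888 cluster separated participants, with 0.723 for miR-891a-5p, 0.559 for miR-888-5p (chromosome X, 145994784 to 145994860) and 0.533 for miR-892a (chromosome X, 145996669 to 145996743). So did 91.7% of all miRNAs.

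Both arms were measured for 31 miRNA precursors, among them miR-34c, miR-30a, miR-21 and miR-148a. Over months within participants the arms had r of 0.346 for miR-34c, 0.636 for miR-30a, 0.514 for miR-21 and 0.729 for miR-148a, and 26 of the 31 pairs lay above 0. The lowest was miR-339, whose arms had -0.52. The median was 0.214, against 0.0527 for random pairs of matched level (1-sided permutation p = 0.0037), and the participant means of the arms had a median r of 0.538.

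A candidate explanation is a shared supply from 1 precursor, which predicts a higher r for arms than for random pairs, as the median of 0.214 was. A technical explanation is also open, namely that reads of 1 arm may have been counted at the complementary arm as well, without regard to strand. The r of the arms rose with the longest perfectly complementary stretch of the hairpin over 30 precursors (Spearman rho = 0.482, permutation p = 0.0072, Pearson r = 0.612), as this explanation predicts. The 4 precursors with a stretch of 15 bases or more were miR-6509 (r = 0.997), miR-4699 (0.936), miR-625 (0.797) and miR-486 (0.539), and the 26 others had a median of 0.198, which was not tested on its own. Neither explanation is excluded, and the high intraclass correlations of both arms of miR-4699 may be 1 signal counted at each arm.

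Some features held identical values in all libraries. These were miR-423-5p and miR-3184-3p, miR-103a-3p and miR-103b, 1 pair of piRNAs and 10 pairs of tRNA genes. The hairpins of miR-423 (chromosome 17, 30117079 to 30117172, plus strand) and miR-3184 (30117086 to 30117160, minus strand) overlap on opposite strands. Identical values from opposite strands are what counting without regard to strand would give at this locus. The other arms of these hairpins, miR-423-3p and miR-3184-5p, were not identical, with means of 4.611 and 4.001 log2 CPM. The tRNA pairs, such as tRNA-Gly-CCC-1-1 and tRNA-Gly-CCC-1-2, are named as copies of the same sequence.

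With array weights, a setting fixed beforehand, the interaction of batch and month called 66 miRNAs, 524 piRNAs and 50 tRNAs. Participants shuffled among batches gave up to 58, 839 and 43 in 10 shuffles with the same weights. The miRNA and tRNA counts thus lay above all 10 shuffles, whose medians were 13.5 and 28, and the piRNA count did not. So few shuffles cannot reach a p under 0.05. The differences between batches with array weights, 191, 958 and 63, were above the highest of the shuffles, 10, 340 and 28.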
